A study of Bombus terrestris with 33 samples.

How the data were processed

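Brain mRNA of 33 queens was sequenced from TruSeq libraries on an Illumina HiSeq 2000, per the labels' protocols. The submitters' processing notes name FastQC, TopHat, SAMtools and edgeR, without versions or roles. The genome build, the annotation and the counting program are not given in the sources used here. The authors deposited a table of raw read counts for 10672 contigs, with whole numbers and 1 column per library, per the file headers. Of these contigs, 1799 had no read in any library. No row was blank or a total, and 0 columns belonged to samples outside the 33.

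The authors also deposited a table of scaled scores and a table of normalized scores with 1 column per group, named for clustering. The scaled scores equal the raw counts after 2 steps, with a largest difference of 7.77e-15. Each library was centred and divided by its SD over contigs, and each contig was then centred and divided by its SD over libraries. The group column of FM in the clustering table equals the FM mean of the scaled scores minus the mean of the 4 group means. The other deposited columns equal the group's mean score minus the column before it, in the order FM, SM, FR, SR, with a largest difference of 8.88e-16. These scores were used only in the closing section and for 1 alternative of the principal components.

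Groups and colonies were taken from the sample labels. The protocols describe separate queens, so the spread between libraries of a group is the spread between queens, some of which share a colony. No pair of libraries agreed within sampling noise. Over the 528 pairs the lowest chi-square per degree of freedom was 82.7, between FR replicates 27 and 28, for contigs with a mean count above 50. Replicate numbers are not shared between groups, so no pairing was used.

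Contigs were filtered with filterByExpr by group (minimum count 10), which left 5606 contigs with 99.99% of the reads. Counts were scaled with TMM and fitted over all 33 libraries with group and colony as terms, by the quasi-likelihood test of edgeR 4.0.16 (robust fit) under R 4.3.3, with Benjamini-Hochberg adjustment and calls at an adjusted p of 0.05. Standard errors are the fold change divided by the square root of the F statistic. Principal components used log2 CPM with a prior count of 2. The comparisons, their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Two-sided permutation tests used scipy 1.17.1, exact for groups under 10 and with 100000 resamples otherwise. They took no account of colony. Intervals are at 95%.

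Contig identifiers matched 0 names of the reference table of 13398 genes, so the planned gene lists, their camera tests and the parts of the naming rule that need product names were not run. The remaining part of the rule named, per comparison, at most 2 contigs higher and 2 lower with the largest fold change among called contigs with a mean of at least 5 CPM and the same direction in every colony that holds both groups. Where fewer than 5 contigs were called, the rule named contigs with the lowest p as values only, and for the difference between stages those with the lowest adjusted p; both were held to the same limit of 2 contigs per direction.

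On simulated counts for the 5606 contigs with 200 changed, the SR versus FR test recovered 47.8% of 1.5-fold, 79.1% of 2-fold and 89.4% of 4-fold changes and called 5 unchanged contigs. The SM versus FM test recovered 65.7%, 85.1% and 93.9% and called 5 unchanged contigs. The SR versus SM test recovered 38.8%, 58.2% and 90.9% and called 3, and the FR versus FM test 50.7%, 64.2% and 92.4% and called 7. The simulated contigs were drawn independently around a mean common to all queens. They held no colony effect and no variation shared between contigs, so these rates need not hold for the real queens.

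Alternatives were DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, DESeq2 size factors or upper-quartile scaling in edgeR, no filter on low counts, a filter of 1 CPM in 8 libraries, no colony term, only the compared groups, a test against a 1.2-fold change, colonies left out and age as a covariate. Leaving out each library, leaving out the 10 most abundant contigs and total counts with no scaling factors were added after the data were seen.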

Results

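Brains of 33 individual queens of the buff-tailed bumblebee, Bombus terrestris, were profiled by mRNA sequencing, with 1 library per queen. Gynes, the virgin females that become queens, were first offered males at 5 days of age. The 9 FM queens failed to mate, and the 8 SM queens mated and were frozen 3 days later. Other mated queens were hibernated for 8 weeks at 5 °C and frozen 1 month after hibernation. Of these, the 8 SR queens had developed ovaries with mature eggs and the 8 FR queens had undeveloped ovaries. FM and SM queens came from colonies C2, C3 and C7, and FR and SR queens from colonies C2, C3 and C9. Total counts ranged from 42858092 to 61560882 per library. The features of the count table are contigs, of which 5606 were tested. None of the 10672 contig identifiers matched the reference gene table, so the contigs are reported without gene names.

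FR queens scored lower on average than SR queens on the first principal component of log2 CPM, which held 27.7% of the variance. The mean score was -25.2 ± 21.9 (SD, n = 8) in FR and 16.3 ± 8.67 (SD, n = 8) in SR queens. The difference passed a two-sided exact permutation test (p = 0.000777, adjusted p = 0.00466 over 6 tests of 2 components). That test moved queens between groups without regard to colony. The group means had the same direction in each colony. Colony C2 had mean scores of -40.0 in FR and 19.9 in SR queens, colony C3 of -26.1 and 20.0, and colony C9 of -1.38 and 10.2, with 2 or 3 queens behind each mean. The groups overlapped in colony C9, where FR replicates 37 and 38 scored 16.3 and -19.1, against -3.19 to 22.9 in SR queens. FM queens had a mean of 3.89 ± 21.2 (SD, n = 9) and SM queens of 4.46 ± 16.0 (SD, n = 8), which differed by less than the spread between queens (exact permutation p = 0.956, adjusted p = 0.956). With FR and SR queens pooled, the mean scores before and after hibernation did not differ on this component (permutation p = 0.285, adjusted p = 0.427). The FR and SR means lay on opposite sides of the FM and SM means, so the pooled test cannot show that the stages are alike. On the second component, with 9.81% of the variance, SM queens scored lower than FM queens by less than the adjusted test required (exact permutation p = 0.0256, adjusted p = 0.0768). FM replicate 6 had a score of 59.8 there, against 14.4 for the next library.

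**Figure D1:**
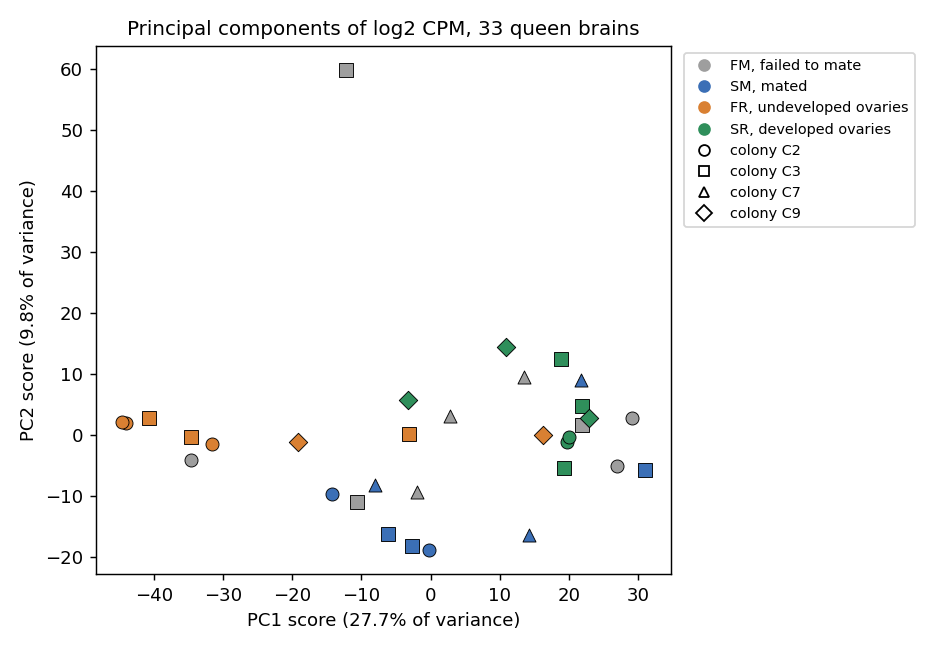
Scores of the 33 libraries on the first (x axis, 27.7% of variance) and second (y axis, 9.81%) principal component of log2 CPM, 1 point per queen, coloured by group with the marker giving the colony. Most FR queens lie at negative PC1 scores, with FR replicate 37 at 16.3, and FM replicate 6 lies alone at 59.8 on PC2.

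The comparison of SR with FR queens asked how brain expression differs between queens that did and did not develop their ovaries after hibernation. Contig735 rose from 93.9 ± 126 CPM in FR to 1606 ± 1298 CPM in SR queens (SD, n = 8 each), a log2 fold change of 4.31 ± 1.31 (SE; edgeR quasi-likelihood test, adjusted p = 0.0170). Contig45 rose from 408 ± 910 to 2459 ± 405 CPM, a log2 fold change of 4.10 ± 1.49 (SE; edgeR adjusted p = 0.0393). Contig3989 fell from 13.4 ± 7.63 to 1.91 ± 0.920 CPM, with a log2 fold change of -2.85 ± 0.69 (SE; edgeR adjusted p = 0.00576). Contig3915 fell from 21.0 ± 11.9 to 3.24 ± 0.953 CPM, with a log2 fold change of -2.49 ± 0.61 (SE; edgeR adjusted p = 0.00589). In all, edgeR called 1652 of the 5606 contigs, 799 higher and 853 lower in SR queens, with a median absolute log2 fold change of 0.46. Of these, 86 were more than 2-fold higher and 242 more than 2-fold lower. The direction was the same in colonies C2, C3 and C9 for 1455 (88.1%), against 38.8% of contigs not called. The calls came from the same queens, so this agreement was partly built in. The 2 most abundant contigs of the table were singled out after their values were seen. The most abundant held 0.988 ± 1.64% of reads in FR and 6.78 ± 3.62% in SR queens, which did not pass the test (log2 fold change 3.06 ± 1.205 SE, edgeR adjusted p = 0.0548). It was called by DESeq2 (log2 fold change 3.07, adjusted p = 0.00206) and by limma-voom (log2 fold change 6.34, adjusted p = 1.15e-05). Without the colony term (2.93, adjusted p = 0.0460) or with a filter of 1 CPM in 8 libraries (3.05, adjusted p = 0.0447) edgeR called it too. It was also called without FM replicate 2, SM replicate 21 or 25, FR replicate 32 or 37, or SR replicate 47, and without FR replicate 32 its log2 fold change was 5.10 (edgeR adjusted p = 0.00932). Over all alternatives its adjusted p ranged up to 0.327. The second most abundant held 3.02 ± 1.25% in FR and 1.06 ± 0.221% in SR queens (log2 fold change -1.201 ± 0.30 SE, edgeR adjusted p = 0.00620).

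The balance of directions depended on the scaling. Upper-quartile scaling gave 574 higher and 1017 lower contigs, and total counts with no scaling factors gave 215 higher and 1537 lower, with a median log2 fold change over all tested contigs of -0.22 in place of -0.04 with TMM. No contig was called without colony C2 (1175 at an unadjusted p under 0.05) or without colony C3 (1435 at an unadjusted p under 0.05), 1960 were called in colonies C2 and C3 alone, and 1099 without SR replicate 39. Without colony C2 and without colony C3 the log2 fold changes were 3.82 and 3.27 for Contig735, 3.08 and 3.25 for Contig45, -2.61 and -2.67 for Contig3989, -2.16 and -2.32 for Contig3915, and -0.93 and -1.18 for the second most abundant contig. The FR mean of Contig45 rests on FR replicate 37, at 2652 CPM against 28.6 to 263 CPM in the other FR queens. Without FR replicate 37 the log2 fold change was 4.85 for Contig45 (edgeR adjusted p = 0.00983) and 5.12 for Contig735 (edgeR adjusted p = 0.00445). The size and call of Contig45 depended on the colony term, without which the log2 fold change was 2.59 (edgeR adjusted p = 0.119). The call was also lost with no filter on low counts (edgeR adjusted p = 0.0675), and without any 1 of FR replicates 27, 28, 31, 32, 33, 36 and 38 or SR replicates 39, 40, 43 and 45, where the log2 fold change stayed between 3.84 and 4.12. Against a minimum of 1.2-fold neither Contig735 (edgeR adjusted p = 0.0594) nor Contig45 (edgeR adjusted p = 0.105) was called. Over all alternatives and tools the adjusted p lay between 3.09e-05 and 0.221 for Contig735 and between 0.000191 and 0.332 for Contig45.

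**Figure D2:**
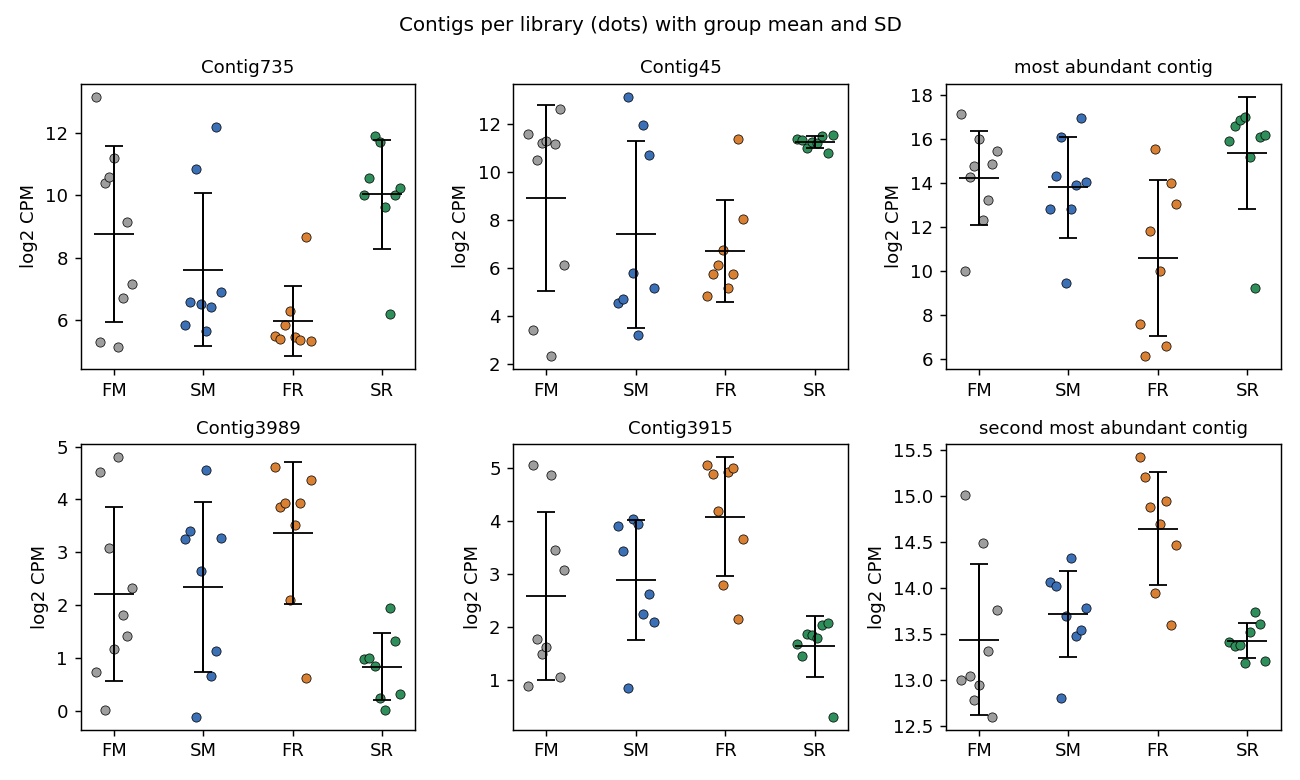
Log2 CPM (y axis) of 6 contigs in each queen (dots), by group (x axis), with the group mean and SD as bars. Contig735 and Contig45 are higher in SR than in FR queens and Contig3989 and Contig3915 lower, while FM and SM queens spread over both levels; the difference in the most abundant contig did not pass the edgeR test (adjusted p = 0.0548).

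The comparison of SM with FM queens asked how brains differ by mating outcome. Contigs with the lowest p are given as values. Contig276 had 0.705 ± 0.183 CPM in FM (SD, n = 9) and 1.43 ± 0.602 CPM in SM queens (SD, n = 8; edgeR adjusted p = 0.133). Contig1969 had 87.7 ± 21.8 CPM in FM and 136 ± 33.8 CPM in SM queens (edgeR adjusted p = 0.229). Contig2661 had 0.798 ± 0.224 CPM in FM and 0.440 ± 0.146 CPM in SM queens, and Contig5702 had 1.22 ± 0.379 and 0.705 ± 0.166 CPM (edgeR adjusted p = 0.229 for both). None of these passed the test. With edgeR 0 contigs were called and 564 had an unadjusted p under 0.05, where the other splits of the same queens gave a median of 338. DESeq2 called 1 contig, Contig276, and limma-voom with quality weights called 0. For contigs at 5 CPM or more, the median 95% interval of a fold change spanned a factor of 1.14 to either side. Leaving out FM replicate 15 gave 13 calls, and leaving out SM replicate 22 or SM replicate 25 gave 1 each. All 4 named contigs passed without FM replicate 15, Contig276 also without SM replicate 22 and Contig1969 without SM replicate 25.

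The test of whether the outcome effect differed between the stages, (SR minus FR) minus (SM minus FM), gave positive log2 differences of 1.29 ± 0.24 for Contig5808 and 1.73 ± 0.33 for Contig4984 (SE). Contig5808 had 5.23 ± 1.56 CPM in FR and 9.35 ± 2.00 CPM in SR queens, against 9.11 ± 3.04 in FM and 6.60 ± 1.60 in SM queens (SD). Negative differences were -0.62 ± 0.12 for Contig2809 and -0.57 ± 0.11 for Contig223 (SE; edgeR adjusted p = 0.0214 for all 4 contigs). Contig2809 had 19.4 ± 1.59 CPM in FR and 14.9 ± 1.33 CPM in SR queens, against 15.7 ± 1.964 in FM and 18.6 ± 2.65 in SM queens (SD). In total 407 contigs were called, 189 positive and 218 negative, with 72 positive and 476 negative under total counts. This count rests on which libraries are included. It moved by over 1.5 times in 27 of the 33 fits that left out 1 library, and it was 0 without FR replicate 38 or SR replicate 39, 4 without FR replicate 33, 5 without FM replicate 2 or SM replicate 22, 9 without FR replicate 28 or SM replicate 26, and 1097 without FR replicate 37. Each of the 4 named contigs lost its call without FR replicate 38 (edgeR adjusted p = 0.0597) and without SR replicate 39 (edgeR adjusted p = 0.0537), while their log2 differences there were 1.23 and 1.22 for Contig5808, 1.72 and 1.73 for Contig4984, -0.59 and -0.58 for Contig2809 and -0.56 and -0.54 for Contig223. With edgeR no contig was called without colony C2 (677 at an unadjusted p under 0.05) or without colony C3 (1022), where the differences were 1.23 and 1.41 for Contig5808, 1.52 and 1.61 for Contig4984, -0.51 and -0.72 for Contig2809 and -0.55 and -0.47 for Contig223. None of the 4 was called against a minimum of 1.2-fold (edgeR adjusted p = 0.0629 for Contig5808 and Contig4984 and 0.122 for Contig2809 and Contig223). Over all alternatives and tools their adjusted p reached 0.343.

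Over the 5606 contigs, the SM minus FM and SR minus FR fold changes had a Pearson r of 0.0311 and a Spearman rho of 0.0433, across contigs, which are not independent replicates. A linear model of log2 CPM gave r = -0.0299. Under that model, random relabelling of outcome within stage and colony gave r between -0.430 and 0.429 in 95% of 100 draws, and 87 of the 100 lay as far from 0. With no contig called between SM and FM queens, no overlap of calls could be counted.

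**Figure D3:**
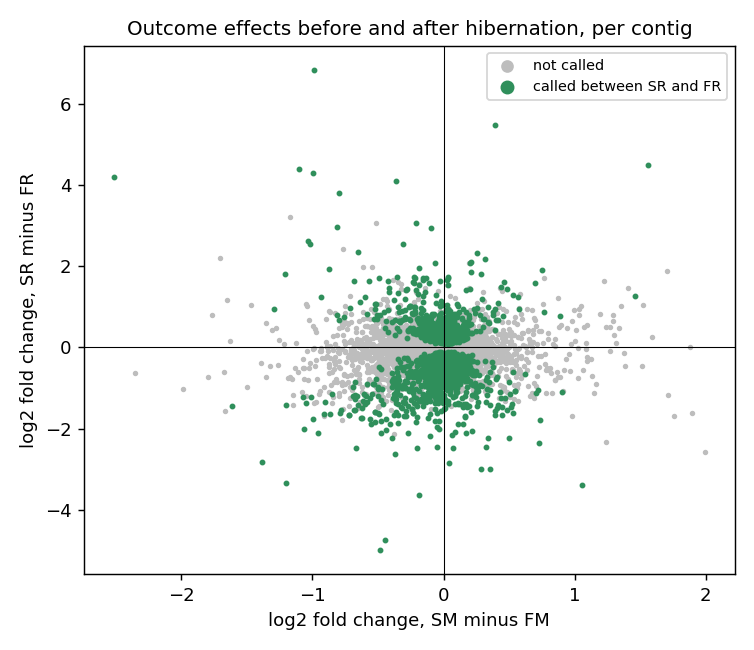
Log2 fold change between SR and FR queens (y axis) against that between SM and FM queens (x axis) for the 5606 tested contigs, with the 1652 contigs called between SR and FR queens in green. The called contigs spread to both sides of the vertical line (r = 0.0311).

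Queens of the FR group were also compared with queens sampled before hibernation, comparisons in which stage, age and hibernation change together. Colony C7 held only queens sampled before hibernation and colony C9 only queens sampled after it. With the colony term, only colonies C2 and C3 therefore link the stages. FR queens had mated and FM queens had not, so the comparison with FM queens also differs in mating. Against FM queens, Contig8577 rose from 4.47 ± 5.55 CPM in FM (SD, n = 9) to 21.2 ± 27.7 CPM in FR queens (SD, n = 8), a log2 fold change of 2.06 ± 0.59 (SE; edgeR adjusted p = 0.0196). Contig4710 rose from 13.3 ± 7.90 to 29.0 ± 15.8 CPM, a log2 fold change of 1.51 ± 0.33 (SE; edgeR adjusted p = 0.00427). Contig735 fell from 1706 ± 2933 to 93.9 ± 126 CPM, with a log2 fold change of -4.48 ± 1.44 (SE; edgeR adjusted p = 0.0342). Contig5138 fell from 16.2 ± 23.1 to 3.19 ± 4.78 CPM, with a log2 fold change of -3.98 ± 1.04 (SE; edgeR adjusted p = 0.0132). In all 970 contigs were called, 471 higher and 499 lower in FR queens, with 600 higher and 364 lower under upper-quartile scaling and 425 higher and 160 lower under total counts. Against SM queens 991 contigs were called, 521 higher and 470 lower in FR queens, with 681 higher and 303 lower under upper-quartile scaling and 480 higher and 155 lower under total counts.

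Both FR counts depended on colonies and single libraries. Without colony C2 they were 3 and 0 (1002 and 1035 at an unadjusted p under 0.05), and without colony C3 2 and 0 (1188 and 997). The count against FM queens was 457 without FR replicate 36, 467 without FR replicate 33, 522 without FR replicate 27, 523 without FR replicate 28 or FM replicate 5, 538 without FM replicate 2, 622 without FM replicate 9 and 1515 without FM replicate 4. The count against SM queens was 435 without FR replicate 36, 502 without FR replicate 33, 504 without FR replicate 27, 526 without SM replicate 19, 549 without SM replicate 16 and 554 without FR replicate 28. Contig8577 lost its call against FM queens without FR replicate 31 or 33 (log2 fold changes of 1.60 and 1.76) and with only the compared groups in the fit (2.18, edgeR adjusted p = 0.0688). Contig5138 lost it without FM replicate 9 (-2.97) and without the colony term, where its log2 fold change was -2.34 (edgeR adjusted p = 0.0566). It kept its call at -5.18 with only the compared groups, -5.17 in colonies C2 and C3 alone and -3.21 under limma-voom. The FM mean of Contig735 rests on FM replicate 2, at 9214 CPM, without which the log2 fold change was -3.07 and the call was lost (edgeR adjusted p = 0.103). The call of Contig735 was also lost with no filter on low counts (edgeR adjusted p = 0.0593) and without FM replicate 5 or 9 or FR replicate 27, 28, 31, 33 or 36, where its log2 fold change stayed between -4.51 and -4.29. Without colony C2 and without colony C3 the log2 fold changes against FM queens were -2.80 and -4.71 for Contig735, -3.28 and -3.32 for Contig5138, 2.13 and 1.89 for Contig8577 and 1.48 and 1.57 for Contig4710, none of which passed. Against a minimum of 1.2-fold, Contig8577, Contig5138 and Contig735 were not called (edgeR adjusted p = 0.0817, 0.0654 and 0.114). Over all alternatives and tools the adjusted p reached 0.164 for Contig8577, 0.260 for Contig5138 and 0.446 for Contig735.

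The comparison of SR with SM queens set successful queens after hibernation against successful queens before it. Here too only colonies C2 and C3 link the stages. The contigs with the lowest p included Contig1669, at 0.316 ± 0.375 CPM in SM and 2.84 ± 1.46 CPM in SR queens (SD, n = 8 each; edgeR adjusted p = 0.0866), and Contig2020, at 4.83 ± 0.782 and 8.94 ± 1.92 CPM (edgeR adjusted p = 0.119). Contig527 had 7.03 ± 2.41 CPM in SM and 4.87 ± 0.583 CPM in SR queens (edgeR adjusted p = 0.0856), and Contig562 had 5.31 ± 0.803 and 3.52 ± 0.759 CPM (edgeR adjusted p = 0.119). None passed the main test. All 4 were called by DESeq2 and by limma-voom with quality weights, with adjusted p from 8.73e-05 to 0.0118. Contig1669 and Contig2020 were called without the colony term, and Contig1669 and Contig527 with only the compared groups or only colonies C2 and C3. Contig1669 was called without FM replicate 14 or 15, SM replicate 25 or FR replicate 37. Contig527 was called without FM replicate 6, 14 or 15, SM replicate 25 or FR replicate 27 or 37, Contig2020 without SM replicate 25, and Contig562 without FM replicate 6 or SM replicate 25. Over all alternatives and tools the adjusted p of each reached 0.999. With edgeR 0 contigs were called and 594 had an unadjusted p under 0.05, where the other splits of the same queens gave a median of 156. Those splits could place queens of colony C7 or C9 in both groups, unlike the real one, so they are not a like reference. DESeq2 called 45 contigs and limma-voom with quality weights 434. Leaving out 1 library gave 18 calls without SM replicate 25, 5 without FM replicate 15, 4 without FR replicate 37, 3 without FM replicate 6, 2 without FM replicate 14 and 1 without FR replicate 27. The SR minus SM and FR minus FM fold changes had a Pearson r of -0.0169 across contigs. In a linear model of log2 CPM the r was -0.0958, and 62 of 100 draws with stage relabelled lay as far from 0.

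Estimated age, read as days, ranged from 6 to 27 in FM and from 11 to 20 in SM queens. Over these 17 queens, age had a Pearson r of -0.192 with the first component (permutation p = 0.463) and a Spearman rho of -0.158 (permutation p = 0.543), each with an adjusted p of 0.835 over 8 tests. Without the 2 queens farthest from the median age, r was -0.0297 (permutation p = 0.916, adjusted p = 0.951). Within FM queens r was -0.319 (exact permutation p = 0.39998, adjusted p = 0.835), and within SM queens r was 0.202 (exact permutation p = 0.626, adjusted p = 0.835).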

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

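Single queens far from the rest of their group were sought in 100 sets of values, each a library measure or a named contig in 1 group. Chance marks about 1 set in 20, so 5 were expected, and 12 sets were marked, some of them by the same queen; the sets are not independent. The statistic is the gap to the nearest queen divided by the range of the group. SR replicate 47, of colony C9, was lowest of the SR queens on the first principal component (0.540), in Contig735 (0.599) and in the most abundant contig (0.770), at -3.19, 6.21 log2 CPM and 9.25 log2 CPM. FM replicate 6 was highest of the FM queens on the second component (0.7104) and in the number of contigs outside the range of all other libraries (0.551), which was 1465 against 758 in the next FM queen. SM replicate 25 was highest of SM queens on the second component (0.529). FR replicate 37 was highest of the FR queens in Contig735 (0.708). The other far queens were the lowest of their groups, SR replicate 49 in Contig3915 (0.646), FR replicate 32 in Contig1669 (0.598), FR replicate 27 in Contig527 (0.665), SR replicate 39 in Contig527 (0.5264) and FM replicate 4 in Contig4984 (0.578).

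In the main fit 407 contigs were called for a difference of SR minus FR from SM minus FM, tested as an interaction. That count moved by over 1.5 times in 27 of 33 fits that left out 1 library. It was 0 without FR replicate 38, SR replicate 39, colony C2 or colony C3. Those named by their low p were Contig5808 (1.29 on the log2 scale), Contig4984 (1.73), Contig2809 (-0.62) and Contig223 (-0.57), and the second most abundant contig gave -1.36 (edgeR adjusted p = 0.0409). That last call was lost in 21 of 33 fits that left out 1 library, where the log2 difference stayed between -1.39 and -1.23. Those libraries were FM replicates 2, 5, 9, 11 and 14, SM replicates 16, 17, 21, 22 and 26, FR replicates 27, 28, 31, 33, 36 and 38, and SR replicates 39, 40, 43, 44 and 45. It was also lost with no filter on low counts (-1.36, edgeR adjusted p = 0.0690), in colonies C2 and C3 only (-1.54, edgeR adjusted p = 0.0562) and against a minimum of 1.2-fold (edgeR adjusted p = 0.136). Without colony C2 it was -1.14 (edgeR adjusted p = 0.355) and without colony C3 -1.37 (edgeR adjusted p = 0.204).

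Other splits of the same libraries, 100 per comparison with the real one, were run to ask how often chance gives as many contigs. They moved queens between groups without regard to colony, and 100 splits cannot resolve a share under 1 in 100. Colonies C7 and C9 each held queens of 1 stage, which drawn splits across stages did not keep, so those are not a like reference. For SR versus FR only the real split reached 1652 calls, and the highest other had 1373. For FR versus FM only the real split reached 970 (highest other 642), and for FR versus SM only the real split reached 991 (highest other 865), so 1 of 100 splits in each was as large. For the difference between stages 2 of 100 splits reached 407 calls, with 607 in the highest other. Those splits moved queens between SR and FR and between SM and FM, which removes the outcome effects themselves. They are therefore not a like reference for a difference of these effects between stages. For SR versus SM 3 of 100 splits reached 594 contigs at an unadjusted p under 0.05, with 807 in the highest other. For SM versus FM 21 of 100 splits reached 564 contigs, with 1024 in the highest other, so chance cannot be excluded there.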

How the results depend on the processing

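Leaving out libraries, the 10 most abundant contigs, and total counts were chosen after the data were seen. The causes of the changes below were not tested, except that leaving out a colony removes libraries and a 1.2-fold minimum is a stricter test. Counts are for SM versus FM, SR versus FR, SR versus SM, FR versus FM, FR versus SM and the difference between stages, and those not given stayed within 1.5 times. DESeq2 gave 1 for SM versus FM, 45 for SR versus SM and 817 for the difference between stages. For the latter, no filter gave 133 and 1 CPM in 8 libraries 615. For SR versus SM, the fit without colony gave 36 and only the compared groups 17; the latter gave 399 for FR versus FM. Limma-voom with quality weights gave 3261 for SR versus FR, 434 for SR versus SM, 2475 for FR versus FM, 2515 for FR versus SM and 2463 for the difference between stages. Tested against 1.2-fold, these were 186 for SR versus FR, 35 for FR versus FM, 19 for FR versus SM and 0 for the difference between stages. Without colony C2 they were 0 for SR versus FR, 3 for FR versus FM, 0 for FR versus SM and 0 for the difference between stages, and without colony C3 0, 2, 0 and 0. In colonies C2 and C3 alone SR versus SM gave 9 and the difference between stages 658. Total counts gave 585 for FR versus FM and 635 for FR versus SM. With each library left out, counts ranged from 0 to 13 for SM versus FM, 1099 to 2132 for SR versus FR, 0 to 18 for SR versus SM, 457 to 1515 for FR versus FM, 435 to 1354 for FR versus SM and 0 to 1097 for the difference between stages. With the deposited scaled scores, the SR versus FR difference on the first component had an adjusted p of 0.0747, while that on the second component passed (0.0270, against 0.353 with log2 CPM). That first component held 83.9% of the variance. Of 8873 contigs with reads, 6896 (77.7%) had scaled scores that correlated over 0.9 with those of contigs without reads. This alternative therefore cannot tell expression from an offset that contigs without reads share. The correlation of outcome effects was -0.274 and that of stage effects -0.192 under limma-voom, where 19 and 23 of 50 relabelled fits of the same kind lay as far from 0. Of 1405 values of named contigs under alternatives, none that was called there or in the main fit reversed its direction. Changes of sign between fits without a call were not counted. The SM minus FM log2 fold change of the most abundant contig went from -0.51 to 0.30 without colony C2. Without FM replicate 2 it was 0.34. Apart from single libraries, 49 of 415 values lost and 22 gained a call. With single libraries left out, 57 of 990 lost and 27 gained one. The gene list tests were not run, as no contig had a name. At this depth 3 counts in the smallest library are 0.0700 CPM.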

Other observations

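The tests of another tissue, of library size, of ovary outcome on the axis and of contigs without reads were chosen after the result was seen. Of the 100 most abundant contigs, which held 38.7% of all reads, 57 were called between SR and FR queens, 36 between FR and FM queens, 27 between FR and SM queens and 17 for the difference between stages, where the shares of all tested contigs were 29.5%, 17.3%, 17.7% and 7.26%. None of the 100 was called between SM and FM or between SR and SM queens, and the difference in shares was not tested. Scaling factors also differed between the groups, with TMM factors of 0.949 ± 0.0740 in SR and 1.08 ± 0.0523 in FR queens (SD, n = 8 each; exact permutation p = 0.00171), while log2 total counts differed by 0.01 (exact permutation p = 0.885).

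SR and FR queens differed along an axis of variation already present among FM and SM queens. Its contig weights were the first component of those queens after removal of group and colony means (27.8% of their variance). Across contigs, they had a Pearson r of 0.794 with the SR minus FR fold change of a linear model on SR and FR queens alone. The 100 relabellings in the same model gave -0.756 to 0.749. Relabelled queens thus came close to that r, so its size alone does not tie the axis to outcome. With the SM minus FM fold change r was 0.0480. With a 95% interval beyond 2-fold, 15 called contigs were higher and 26 lower, which argues against RNA of 1 other tissue as the only source. Added RNA of 1 tissue moves contigs far to 1 side. These contigs were picked from those called, and such RNA could still account for a part of the difference. The 100 most abundant contigs leaned to 1 side, with 40 called higher and 17 lower in SR queens. The values argue against library size, since the axis score had r = -0.110 with log2 total count (permutation p = 0.542). The Spearman rho was -0.137 (permutation p = 0.447). Leaving out the 10 most abundant contigs gave 1644 calls. TMM trims the most abundant contigs anyway, so that refit cannot decide whether a few abundant contigs shift the scaling. Total counts with no scaling factors gave 1752 calls, 215 higher and 1537 lower. With the axis score as a covariate 0 contigs were called with edgeR (368 at an unadjusted p under 0.05), as the median absolute log2 fold change of the 1652 contigs shrank from 0.46 to 0.15 while their median SE went from 0.134 to 0.123; a covariate that differs between the groups also absorbs what it shares with them. Ovary outcome stays open, since the axis score had an r of 0.979 with the first component of all libraries, and its difference between FR (-19.6 ± 16.9) and SR queens (14.9 ± 7.42, SD, n = 8 each, exact permutation p = 0.000777) repeats the one already seen there; tissues of more than 1 kind, feeding and the moment of sampling were not tested.

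Contigs without a single read differed between groups in the deposited scaled table, with a mean of 0.744 ± 1.05 in SR and -0.306 ± 0.469 in FR queens (SD, n = 8 each; exact permutation p = 0.0246). Such a contig starts as minus the library mean over the library SD, so its difference comes from the scaling and not from its own expression. A candidate explanation is division by an SD that the most abundant contig sets. The SD was 41936 ± 13995 in SR and 28548 ± 2674 in FR queens (SD over 8 queens each, exact permutation p = 0.0138). The library mean was 4694 ± 369 and 4667 ± 346 counts (exact permutation p = 0.880). Before each contig is divided by its SD over libraries, the SR minus FR difference was 0.0414, and without that contig it turned to -0.0207, which is -50.0% of it, as the SD was then lower in SR (22924 ± 1919) than in FR queens (27334 ± 3499, n = 8 each, exact permutation p = 0.00777). Without the 2 most abundant contigs the difference was 0.00424 (exact permutation p = 0.534, n = 8 each). Why those 2 contigs vary between queens was not tested. The sign of SR minus FR in the scaled table was opposite to that of the fold change in 3115 of the 5606 tested contigs, in 566 of the 853 called lower and in 323 of the 799 called higher.

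In the clustering table the columns had a Pearson r over contigs with the mean scaled score of their own group of 1.00 for FM, 0.884 for SM, 0.651 for FR and 0.894 for SR.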
